A study of Mus musculus with 6 samples.

How the data were processed

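RNA from 6 liver samples of female C57BL/6 mice was analysed, 3 controls (Ctr) and 3 with an induced knockout of Nbs1 (Nbs1-iKO). Per the labels' protocols, each sample was a piece of about 200 mg from the left lateral lobe, total RNA was isolated with Tri Reagent, and libraries were made with the TruSeq RNA v2 kit. That kit selects polyadenylated RNA and does not mark the strand of origin, so reads from a gene and from an antisense or overlapping partner cannot be told apart. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.1.0, featureCounts 1.5.0 and the build GRCm38. The annotation release, the setting for reads with several matches and the authors' statistical test are not given in the sources used here. Reads shared between paralogs, pseudogenes or overlapping genes may therefore have been dropped or split.

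Per the labels of its sheets, the deposited workbook held raw read counts per Ensembl gene, RPM and RPKM for the same 6 libraries. The deposited counts were whole numbers for 53801 genes and were the values tested. The deposited RPM equalled CPM computed from the column total without TMM scaling, with a largest difference of 4.7e-10. The deposited RPKM implied 1 length per gene in all libraries, with a largest relative spread of 1.6e-14, and neither normalised table was used further. A symbol was blank for 66 genes, which held between 0.000915% and 0.000958% of each library's counts and are called by their identifiers. Gene coordinates came from GENCODE M21 on GRCm38, in which 53706 of the deposited identifiers and 17292 of the 17300 tested ones were found.

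Each library's group and replicate number came from its title in the labels. The labels do not state outright that each sample came from a different mouse, so p-values measure the spread between these samples. Counts of each pair of libraries differed far beyond sampling noise, with a chi-square per degree of freedom of 24.8 or more, and no library was counted as a repeat of another.

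Tests used R 4.3.3. The main test was the quasi-likelihood test of edgeR 4.0.16 with robust dispersions, TMM factors and the filterByExpr filter, which kept 17300 genes. Its p-values were adjusted by the Benjamini-Hochberg method over these genes, with a threshold of 0.05 and no limit on the fold. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic, and intervals cover 95%. Fold changes are given as Nbs1-iKO over Ctr, and levels as CPM, the usual count scaled to library size, with TMM scaling, as mean ± SD over 3 libraries per group. DESeq2 1.42.0 and limma-voom from limma 3.58.1 were the alternative tools. Total counts ranged from 34353104 to 50573544 per library, so that 3 counts stood for 0.0593 to 0.0873 CPM, a floor that covers counting error only. The median half-width of the interval of a log2 fold change was 0.25 for genes with a mean CPM of at least 1. These intervals come from the fitted model and cover counting error and the spread between these libraries.

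The fitting code was tested on simulated counts drawn for the same 17300 genes from their means, dispersions and library sizes, with 200 genes of at least 1 CPM changed. For Nbs1-iKO against Ctr, edgeR recovered 44.5% of genes changed 1.5-fold, 89.5% of those changed 2-fold and 98.5% of those changed 4-fold, with 12, 24 and 14 false calls. With no gene changed, edgeR made 4 calls, DESeq2 36 and limma-voom 1. With 1 list of 25 genes raised 1.3-fold, camera with the preset correlation called that list and none of the other lists, at an adjusted p of 3.33e-13. The same list had adjusted p = 0.0681 with an estimated correlation and 0.0672 with fry, so that those tests missed a shift of this size. The simulated genes were drawn independently of each other. In the deposited data the estimated correlation was 0.784 for this list, of cholesterol synthesis. Over the 12 lists called with the preset correlation it ran from -0.012 to 0.878. The simulation therefore does not show how often the preset correlation calls unmoved lists in these data.

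There were 37 gene lists, 21 of pathways and 16 of cell types, written from textbook knowledge before the data were examined. The 34 with at least 5 tested members were tested with camera from limma on log2 CPM with a prior count of 3. A preset correlation of 0.01 between genes was the main setting, and an estimated correlation and fry were alternatives. These p-values were adjusted over the 34 lists. For single members, counts are given over all genes and adjusted over the list alone.

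Also set before the data were examined were the design, the alternatives and the rule for named genes. The rule took Nbn, then up to 8 genes per direction with the largest change past the threshold, and up to 4 members per list with the smallest p. The genes per direction needed a mean CPM of at least 1, groups that did not overlap, and no predicted-gene, clone or pseudogene symbol. Where no gene passed in a direction, the rule took the 5 with the smallest p that met these conditions. The values of some genes that the rule took are not reported here. Any gene named outside the rule is said to have been chosen after its values were seen. Alternatives were other size factors, filters, tools and thresholds, a block for the replicate number or the birth date, the 4 samples of the commoner birth date, and each library left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.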

Results

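Liver RNA was sequenced from 3 Ctr and 3 Nbs1-iKO samples to compare mice that keep 1 intact copy of Nbs1 with mice in which both copies can be deleted. Nbs1, whose gene symbol is Nbn, encodes a subunit of the MRE11-RAD50-NBS1 complex, which binds DNA double-strand breaks and activates the ATM kinase. All samples came from mice with Rosa26-CreERT2, a Cre recombinase that becomes active when tamoxifen is given. Tamoxifen was injected on 5 consecutive days at 1 mg per 25 g of body weight, and tissue was collected 3 days after the last injection. Ctr mice were heterozygous for the floxed allele and so kept 1 intact copy after recombination, whereas Nbs1-iKO mice were homozygous for it. The total gene counts were 41679232, 34353104 and 50573544 in Ctr 1, 2 and 3, and 45816081, 43032419 and 37521666 in Nbs1-iKO 1, 2 and 3. From the dates of birth and death in the labels, the mice of Ctr 3 and Nbs1-iKO 1 were 74 days old and the others 100 days old.

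Nbn, the targeted gene, fell in Nbs1-iKO livers to 30.6% of the Ctr level (95% interval 26.0% to 36.0%). The libraries Ctr 1, 2 and 3 held 434, 296 and 461 Nbn counts, or 10.2, 9.03 and 9.19 CPM. Nbs1-iKO 1, 2 and 3 held 127, 131 and 111 counts, or 2.71, 2.97 and 3.01 CPM. The means were 9.46 ± 0.62 CPM in Ctr and 2.90 ± 0.16 CPM in Nbs1-iKO (SD, n = 3 each). The log2 fold change was -1.71 (SE 0.10, 95% interval -1.94 to -1.47, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00292). Nbn (ENSMUSG00000028224) lies on the plus strand of chromosome 4 at positions 15957925 to 15992589 of GRCm38, and its counts cover all annotated exons, so transcripts that lack only a floxed part are still counted. The labels do not say which exon is floxed. The extent of recombination was not measured, so the remaining counts cannot be divided between recombined and intact copies. Among the 4 samples of the commoner birth date the log2 fold change was -1.68 with an adjusted p of 0.108, and the other date held 1 sample per group. Without Nbs1-iKO 2 the adjusted p was 0.0523 at a log2 fold change of -1.73, and over all 17 alternatives the adjusted p ranged from 2.62e-25 to 0.108.

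**Figure D1:**
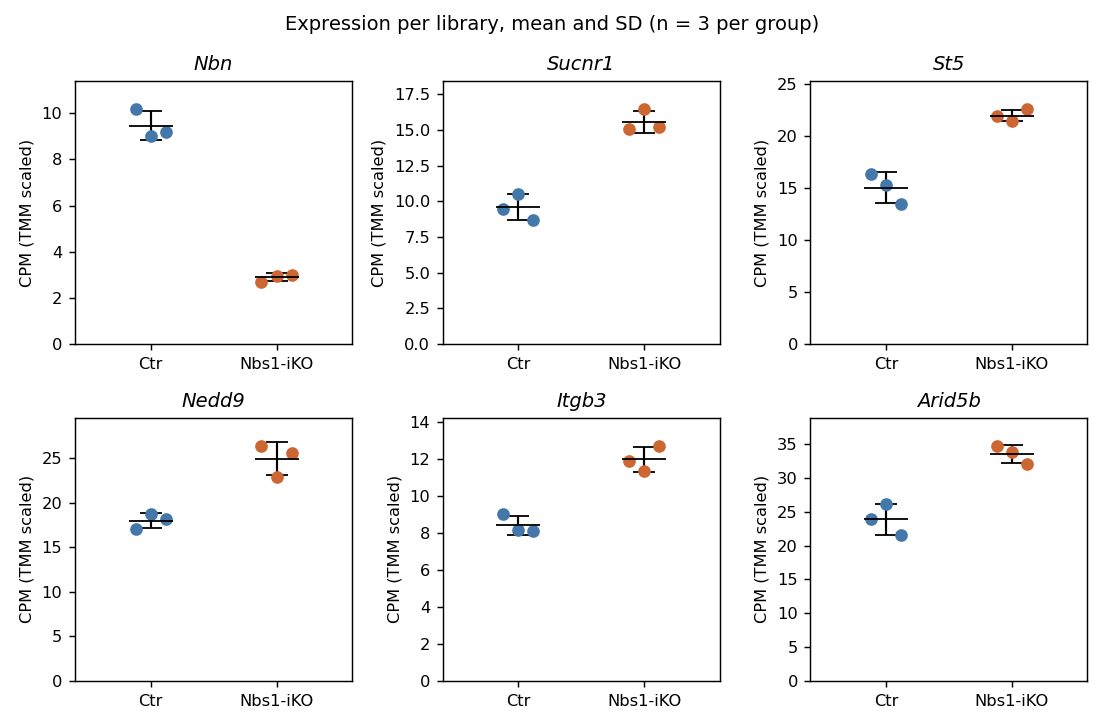
CPM (TMM scaled) of Nbn and of the 5 named genes with the smallest p among those higher in Nbs1-iKO, with points for libraries and bars for mean and SD (n = 3 per group). Nbn stood between 2.71 and 3.01 CPM in Nbs1-iKO and between 9.03 and 10.2 CPM in Ctr, and the 5 other genes did not pass the adjusted threshold in edgeR with the filter on low counts.

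Nbn was the only gene that passed the threshold among the 17300 tested with edgeR, which called 0 genes higher and 1 lower. At an unadjusted p under 0.05, 531 genes were higher and 507 lower, 1038 in all. That is above the 865 of evenly spread p-values, but other splits of the same 6 libraries into 3 and 3 gave 340 to 1275. DESeq2 called 23 genes higher and 29 lower, and limma-voom 0 and 1, while on simulated counts with no changed gene DESeq2 made 36 calls and edgeR 4. With 1 library left out, edgeR called 0 to 2 genes higher (2 without Nbs1-iKO 3, 1 without Nbs1-iKO 1) and 0 to 3 lower (0 without Nbs1-iKO 2, 2 without Ctr 2, 3 without Nbs1-iKO 1). The groups of 3 did not overlap for 11.6% of genes, where chance gives 10%. The second principal component of log2 CPM, with 21.4% of the variance, ran from -19.1 to -12.6 in Ctr and from 6.4 to 26.3 in Nbs1-iKO. The first, with 33.2%, set Ctr 1 at -36.9 against Ctr 2 at 30, with the other libraries between -5.3 and 9.6.

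Of the genes with higher levels in Nbs1-iKO, Sucnr1, Itgb3, Nedd9, St5 and Arid5b had the smallest p-values under the rule for named genes, and none passed the adjusted threshold in edgeR with the filter on low counts. Without that filter edgeR called Sucnr1 (adjusted p = 0.00384), St5 (0.018), Arid5b (0.0362) and Nedd9 (0.0448). Sucnr1, the cell surface receptor for succinate, stood at 9.57 ± 0.91 CPM in Ctr and 15.6 ± 0.76 CPM in Nbs1-iKO (log2 fold change 0.71, adjusted p = 0.202). St5 stood at 15.1 ± 1.5 and 22.0 ± 0.57 CPM (log2 fold change 0.55, adjusted p = 0.277). Itgb3, the integrin beta 3 subunit carried by platelets and other cells, had a log2 fold change of 0.51, and Nedd9, a scaffold protein of focal adhesions, 0.47. Arid5b, a DNA-binding protein, had 0.49. The rule asked for groups that do not overlap, so every Nbs1-iKO library lay above every Ctr library in these 5 genes by selection. DESeq2 called all 5, with adjusted p from 9.53e-06 for Sucnr1 to 0.0158 for Itgb3.

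Gene lists of the DNA damage response were called neither higher nor lower. The 34 measured p53 target genes had a median log2 fold change of -0.006, a mean of 0.014 and a camera test that leaned lower (adjusted p = 0.99), so the signs differed. No p53 target passed over all genes tested, and 2 were lower when adjusted over the list alone. These were Gdf15, a secreted cytokine that several stress pathways induce, at 53.9 ± 5.9 CPM in Ctr and 29.0 ± 5.3 CPM in Nbs1-iKO (log2 fold change -0.89), and Aen, an apoptosis-linked nuclease, at 17.0 ± 1.0 and 12.2 ± 1.1 CPM (-0.48). DESeq2 called both, at adjusted p = 8.1e-06 and 0.0304. Bbc3, which encodes the apoptosis inducer PUMA, had a log2 fold change of 0.64, and Mdm2, which encodes the main negative regulator of p53, had -0.22, and neither passed. Median log2 fold changes were -0.03 for 24 genes of checkpoint signalling, -0.03 for 27 of homologous recombination and the Fanconi anaemia pathway, and 0.01 for 15 of non-homologous end joining, where the mean and the test leaned lower. None of these lists or their members passed, and the fry test for both directions gave unadjusted p = 0.71, 0.92 and 0.60. For the p53 targets that fry test gave unadjusted p = 0.00367, with 2 members higher and 4 lower at an unadjusted edgeR p under 0.05. That p was not adjusted over the lists, among which the shared hepatocyte genes had the smallest in this fry test, 0.000103. Rad50 and Mre11a, whose products are the partners of NBS1, and Atm were looked up after the data were seen and had log2 fold changes of -0.03, -0.09 and -0.02.

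Immediate early genes and stress response genes stood lower in Nbs1-iKO as lists. The 18 measured immediate early and heat shock genes had a median log2 fold change of -0.17, with 11 below 0 and 7 above (camera, adjusted p = 0.0318, but adjusted p = 0.76 with an estimated correlation). None passed over all genes in edgeR with all libraries, and 4 were lower when adjusted over the list alone, namely Dusp1, Jun, Zfp36 and Ier2. In camera with the estimated correlation, 0.76 was the smallest adjusted p of the 34 lists. All 12 lists called with the preset correlation shared it. Their unadjusted p-values in that setting ran from 0.0464 for immediate early and heat shock genes to 0.604 for mitosis and G2/M genes. Dusp1, a phosphatase that switches off MAP kinases, stood at 90.3 ± 8.3 CPM in Ctr and 34.5 ± 9.4 CPM in Nbs1-iKO (log2 fold change -1.39, adjusted p = 0.277 in edgeR and 2.76e-11 in DESeq2), and without Nbs1-iKO 1 edgeR called it (-1.63, 0.0121). Jun, a subunit of the transcription factor AP-1, had a log2 fold change of -0.53, Zfp36, which promotes decay of AU-rich mRNAs, -0.34, and Ier2 -0.48. All 22 measured genes of the unfolded protein and integrated stress responses had fold changes below 0, with a median of -0.25 (adjusted p = 4.71e-05, but adjusted p = 0.76 with an estimated correlation). Their members Atf4, a transcription factor of the integrated stress response, had -0.31, Atf3 -0.82, Xbp1 -0.24 and Dnajb9 -0.44, and no member passed over all genes or adjusted over the list alone. The preset call of the immediate early list was lost without each of Ctr 1, Ctr 3, Nbs1-iKO 1 and Nbs1-iKO 3 (adjusted p up to 0.246) and with the replicate block (0.0573), and its median was -0.04 without Ctr 1 and -0.08 without Nbs1-iKO 3. The call of the stress list was lost without Ctr 1 (0.0509), where its median was -0.13 with 6 of 22 above 0, and the median was -0.38 without Ctr 2. The groups overlapped in the mean of the stress list. On the log2 scale it stood at 0.45, -0.16 and 0.11 in Ctr 1, 2 and 3 and at -0.24, 0.10 and -0.27 in Nbs1-iKO 1, 2 and 3.

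**Figure D2:**
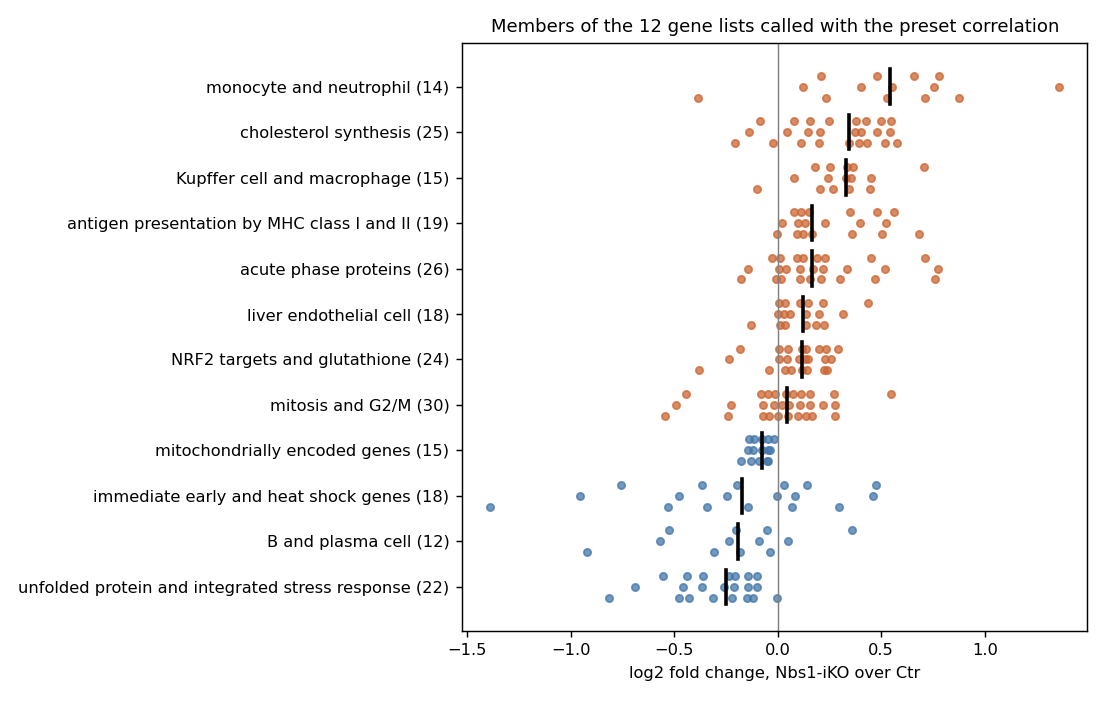
Log2 fold changes (Nbs1-iKO over Ctr) of the members of the 12 lists called by camera with the preset correlation, with the number of tested members in parentheses, a point per gene, black bars for medians, orange for lists called higher and blue for lists called lower. Medians ran from -0.25 for the unfolded protein and integrated stress response to 0.54 for monocyte and neutrophil genes, and no list was called with an estimated correlation.

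Genes of cholesterol synthesis stood higher in Nbs1-iKO as a list, with a median log2 fold change of 0.34 and 21 of 25 members above 0 (adjusted p = 2.3e-05, but adjusted p = 0.76 with an estimated correlation). Tm7sf2 (0.34) and Nsdhl (0.58) encode enzymes of the pathway, and Srebf2 (0.20) encodes its main transcription factor, and none of the 25 passed over all genes or adjusted over the list alone. The groups overlapped in the mean of this list, with Ctr 2 lowest at -0.51 and Ctr 3 at 0.22 on the log2 scale against -0.03 to 0.31 in Nbs1-iKO, and the median was 0.18 without Ctr 2 and 0.18 without Nbs1-iKO 3. Acute phase proteins, which the liver secretes in inflammation, had a median of 0.16 with 22 of 26 above 0 (adjusted p = 0.00512, but adjusted p = 0.76 with an estimated correlation). Among them Saa4 had 0.45 and Orm2 0.33. NRF2 target and glutathione genes had a median of 0.11 with 20 of 24 above 0 (adjusted p = 0.0085, and adjusted p = 0.76 with an estimated correlation), among them Gstm4 with 0.26 and Ugdh with 0.29. The 15 mitochondrially encoded genes were all below 0, with a median of -0.08 (adjusted p = 0.0334, and adjusted p = 0.76 with an estimated correlation). The preset call was lost without Nbs1-iKO 2 or 3 for acute phase proteins (adjusted p up to 0.0926), whose median ran from 0.09 without Nbs1-iKO 3 and 0.10 without Ctr 2 to 0.265 without Ctr 3, and without Ctr 3 or Nbs1-iKO 2 for NRF2 targets (up to 0.196). It was lost without Ctr 2, Nbs1-iKO 2 or Nbs1-iKO 3 for the mitochondrially encoded genes (up to 0.734), whose median was -0.02 without Ctr 2 and -0.12 without Ctr 1.

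Lists of other liver functions were not called. Medians were 0.09 for fatty acid synthesis, 0.07 for fatty acid oxidation and PPARalpha targets, 0.07 for gluconeogenesis and fasting, 0.07 for xenobiotic metabolism, 0.04 for bile acid synthesis and transport, and -0.07 for the circadian clock. Acacb, which encodes an acetyl-CoA carboxylase, was higher when adjusted over its list alone, at 56.0 ± 5.0 CPM in Ctr and 73.5 ± 2.9 CPM in Nbs1-iKO (log2 fold change 0.39). The clock output gene Dbp was lower when adjusted over its list alone, at 8.75 ± 1.7 and 5.58 ± 0.52 CPM (-0.65). Neither passed over all genes in edgeR, while DESeq2 called Acacb (adjusted p = 0.024) but not Dbp (0.0786). Igfbp1, a hepatocyte gene that insulin represses, stood at 27.9 ± 2.5 and 73.5 ± 34.2 CPM (1.40), Irs2, an adaptor of the insulin receptor, at 7.96 ± 2.7 and 17.6 ± 5.4 CPM (1.15), and Angptl4, a lipase inhibitor, at 59.6 ± 10.8 and 89.6 ± 12.3 CPM (0.59). Fgf21, a hormone secreted by the liver, stood at 5.52 ± 0.98 and 3.33 ± 0.55 CPM (-0.73). None of these 4 genes passed in edgeR with all libraries, Igfbp1 passed without Nbs1-iKO 1 (1.73, adjusted p = 0.0121), and DESeq2 called Irs2 (adjusted p = 0.0181) and Angptl4 (0.0338). The type I interferon list had a median of 0.02, and that of NF-kappaB targets and inflammatory cytokines had a median of -0.003 and a mean of -0.03 while its camera test leaned higher (adjusted p = 0.99).

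Of the 5 marker lists of immune cells, 2 were called higher in Nbs1-iKO, those of monocytes and neutrophils and of Kupffer cells and macrophages, and that of B and plasma cells was called lower. Monocyte and neutrophil genes had a median log2 fold change of 0.54 with 13 of 14 above 0 (adjusted p = 4.71e-05, but adjusted p = 0.76 with an estimated correlation), with the granule gene Mmp8 at 1.36 and the calcium-binding S100a8 at 0.87. Mmp8 lay near the floor, at 0.14 ± 0.08 CPM in Ctr and 0.39 ± 0.12 CPM in Nbs1-iKO. In Ctr 2 it stood at 0.061 CPM, below the 0.0873 CPM that 3 counts stand for there. Ctr 2 stood alone in the mean of this list, at -0.90 on the log2 scale against 0.08 and -0.004 in the other Ctr libraries and 0.02 to 0.46 in Nbs1-iKO, and without it the difference of the group means went from 0.55 to 0.23. Kupffer cell and macrophage genes had a median of 0.33 with 14 of 15 above 0 (adjusted p = 0.000152, but adjusted p = 0.76 with an estimated correlation). Clec4f, a Kupffer cell lectin, stood at 181 ± 36 CPM in Ctr and 248 ± 43 CPM in Nbs1-iKO, and the scavenger receptor Cd163 at 56.3 ± 20 and 91.9 ± 26 CPM. Antigen presentation genes had a median of 0.17 with 18 of 19 above 0 (adjusted p = 5.59e-05, and adjusted p = 0.76 with an estimated correlation), including the transactivators Nlrc5 (0.48) and Ciita (0.68). Nbs1-iKO 3 stood apart in the mean of that list, at 0.38 against -0.004 and 0.003 in Nbs1-iKO 1 and 2 and -0.22 to -0.07 in Ctr, and the median was 0.09 without Nbs1-iKO 3 and 0.29 without Ctr 1. Liver endothelial genes had a median of 0.12 with 16 of 18 above 0 (adjusted p = 0.00512, and adjusted p = 0.76 with an estimated correlation), with the scavenger receptors Stab1 at 0.31 and Stab2 at 0.18. B and plasma cell genes had a median of -0.19 with 10 of 12 below 0 (adjusted p = 0.0479, and adjusted p = 0.76 with an estimated correlation), with Jchain at -0.92 and Igkc at -0.57. Itgb3 was higher when adjusted over the 4 platelet genes alone, and Cfd over the 3 adipocyte genes alone, at 0.20 ± 0.09 and 0.62 ± 0.34 CPM. No other member of these lists passed, over all genes or adjusted over the list alone. The preset call was lost without Ctr 2 for Kupffer cells (adjusted p = 0.096), whose median was 0.12 without Ctr 2, 0.18 without Nbs1-iKO 3 and 0.54 without Ctr 1, and without Ctr 2 or Nbs1-iKO 1 for endothelial cells (up to 0.0949), whose median was 0.08 without Ctr 2. It was lost without Ctr 1, Ctr 2, Nbs1-iKO 2 or Nbs1-iKO 3 for B and plasma cells (up to 0.377), whose median was -0.12 without Nbs1-iKO 3 and -0.37 without Ctr 3.

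The remaining cell type lists were not called. Hepatocyte medians were -0.03 for 12 shared genes, 0.05 for 12 periportal genes and 0.03 for 14 pericentral genes, where the mean and the test leaned lower. The share of all counts from Alb lay between 14.3% and 15.6% in Ctr and between 13.4% and 14.0% in Nbs1-iKO. Medians were 0.07 for T and NK cells, 0.10 for dendritic cells, -0.09 for stellate cells and fibroblasts, -0.37 for erythroid cells, -0.32 for mesothelium and -1.10 for bile duct cells. The low bile duct median went with Ctr 1, where Krt19, a keratin of bile duct epithelium, stood at 17.9 CPM against 0.95 to 1.49 CPM in the other 5 libraries. The 2 measured pancreas genes, Cela1 and Amy2b, had -0.73 and 0.09.

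**Figure D3:**
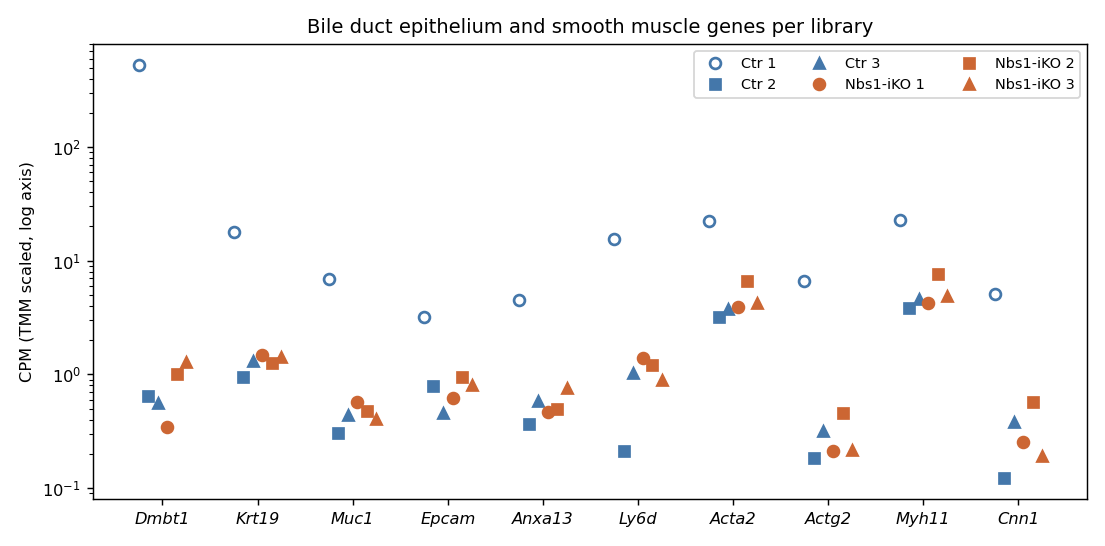
CPM (TMM scaled, log axis) of bile duct epithelium genes and of the smooth muscle genes Acta2, Actg2, Myh11 and Cnn1 in each library (1 point each), with the genes chosen after the data were seen because they stood high in Ctr 1. Ctr 1 (open circles) stood above the other 5 libraries for each gene shown, with Krt19 at 17.9 CPM.

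Cell division genes differed widely among the Ctr libraries. The 30 measured genes of mitosis and G2/M had a median log2 fold change of 0.04 (adjusted p = 0.0336, but adjusted p = 0.76 with an estimated correlation), and none passed over all genes or adjusted over the list alone. Their mean deviation from the average library was 1.07 on the log2 scale in Ctr 1, -1.07 in Ctr 2 and -0.48 in Ctr 3, and it lay between -0.15 and 0.36 in Nbs1-iKO. Without Ctr 2 the list leaned lower (adjusted p = 0.596), and its call was also lost without Ctr 3, Nbs1-iKO 1 or Nbs1-iKO 2 and with the birth date as a block (0.0518). Its median was 1.06 without Ctr 1 and 0.15 without Nbs1-iKO 3, and it lay below 0 in the other 4 cases, at -0.29 without Ctr 2, -0.25 without Ctr 3, -0.07 without Nbs1-iKO 1 and -0.05 without Nbs1-iKO 2. Genes of DNA replication and G1/S had a median of -0.08 and were not called, with Ccne1, which encodes cyclin E1, at -0.52 and Cdc6 at -0.85.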

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

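Nbn kept its direction in all 17 alternatives and stayed past the threshold in 14. It missed with the replicate block (log2 fold change -1.71, adjusted p = 0.0795), which leaves fewer residual degrees of freedom, among the 4 samples of the commoner birth date (-1.68), where fewer samples were tested, and without Nbs1-iKO 2 (-1.73). Leaving out each library in turn moved it between -1.74 and -1.65. The replicate numbers showed no pairing, as deviations of same-numbered libraries correlated at 0.004, -0.07 and -0.05 and 0 of 6 libraries correlated best with their own number. The highest correlations between groups were 0.18 (Ctr 2 with Nbs1-iKO 3), 0.15 (Ctr 3 with Nbs1-iKO 1) and 0.13 (Ctr 1 with Nbs1-iKO 2), each within a birth date. The other pairs between groups within a birth date had -0.13 and -0.07. The replicate block gave 0 genes lower, and so did the 4 samples. Without a filter on low counts 7 genes were higher and 7 lower, and DESeq2 called 23 higher and 29 lower, and the cause was not tested. Leaving out 1 library gave 0 to 2 genes higher (2 without Nbs1-iKO 3) and 0 to 3 lower (0 without Nbs1-iKO 2, 2 without Ctr 2, 3 without Nbs1-iKO 1). Of 2490 pairs of a named gene and a setting, 23 changed sign, none with a call, and 17 came past the threshold, 11 of them in DESeq2. The 12 list calls became 0 with an estimated correlation and 0 with fry, and 7 to 15 with 1 library left out (7 without Nbs1-iKO 2). Of 474 pairs of a list and a setting, 53 lost a call, 19 gained one and 33 changed direction. The adjusted p of the mitosis and G2/M list ran from 6.17e-22 without Ctr 1 to 0.596 without Ctr 2, where its direction reversed. The mean of that list stood at 1.07 in Ctr 1 and -1.07 in Ctr 2 on the log2 scale, so leaving out either library moves the Ctr mean. Why these libraries differ was not tested. Low counts limit precision, with a median interval half-width of 0.25 for genes of at least 1 CPM and 0.19 for those of at least 10 CPM.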

Other observations

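The gene groups named next were put together after the data were seen, and the tests chosen only after their results were seen were those of the chromosome 15 stretch other than its count of splits, those of Ctr 1, and the counts of splits for numbers of genes and lists. Feedback regulators and targets of the ERK kinase pathway stood lower in Nbs1-iKO, with 21 of 26 members below 0 and a median log2 fold change of -0.22. Spry4, an inhibitor of this pathway, stood at 12.8, 9.85 and 11.4 CPM in Ctr 1, 2 and 3 and at 5.17, 6.67 and 5.32 CPM in Nbs1-iKO 1, 2 and 3 (log2 fold change -0.99, SE 0.14). Dusp6, a phosphatase of ERK, had a log2 fold change of -0.66, and Ccnd1, which encodes cyclin D1, -0.76. In edgeR with the filter on low counts and all libraries none of the 26 passed over all genes (9 were lower and 0 higher at an unadjusted p under 0.05). Without the filter edgeR called Spry4 (adjusted p = 0.00301), without Nbs1-iKO 1 it called Dusp1 (0.0121), and DESeq2 called Dusp1, Spry4, Dusp6 and Ccnd1, of which Dusp1 is also in the immediate early list. The test of the ERK list gave p = 0.0201 in camera with an estimated correlation, not adjusted over lists, as for the next lists. The adjusted p-values of the lists written beforehand are another measure. The smallest unadjusted p of those lists in that setting was 0.0464. Since the ERK list and the next ones were chosen from these data, their tests are no independent evidence. Genes of ribosome biogenesis were below 0 in 38 of 40 cases, with a median of -0.16, 18 of them at an unadjusted p under 0.05, with no call in edgeR or DESeq2. Nolc1 had -0.33, Nop56 -0.36, Wdr43 -0.33 and Polr1b, a subunit of RNA polymerase I, -0.32 (camera p = 0.0147 with an estimated correlation). Targets of FOXO transcription factors, which insulin signalling restrains, were above 0 in 17 of 20 cases with a median of 0.14, which ran from 0.11 without Nbs1-iKO 3 to 0.25 without Nbs1-iKO 1. Irs2 had 1.15, Ccng2 0.87 and Klhl24 0.40, and edgeR called none of the 20 (7 higher and 1 lower at an unadjusted p under 0.05) while DESeq2 called Irs2 and Ccng2 (camera p = 0.0682 with an estimated correlation).

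The ERK pattern may reflect the loss of Nbs1, the state of single animals or chance. Without each library in turn the median stayed at or below -0.20, but the members were picked after their values were seen, so this does not exclude a single library as the source. The 10 splits of the 6 libraries are too few for a share under 0.05, and lists picked from the real grouping favour it over the other splits. The real grouping was the 1 split with so small a p, 0.0201, and the smallest p of the other splits was 0.193. For ribosome biogenesis the real p was 0.0147 and the smallest other 0.330, and for FOXO targets 0.0682 and 0.159, so that for each list 1 of the 10 splits, the real one, gave so small a p. Time of feeding and of tissue collection, which could also set these genes, was not tested.

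Genes with a low p gathered in 1 stretch of chromosome 15, from 30 to 35 Mb of GRCm38. There 9 of 28 tested genes had an unadjusted p under 0.01, or 32.1% against 1.35% of all genes. They were Dap, Fam173b, Gm49284, Snhg18, Cpq and Rpl30, lower in Nbs1-iKO, and Ropn1l, Tspyl5 and Laptm4b, higher. None passed the adjusted threshold in edgeR with the filter on low counts, without which it called Laptm4b and Rpl30, and DESeq2 called these along with Tspyl5, Cpq and Fam173b. Placement of independent genes at random is argued against only for the full set of libraries and this grid of windows. A share of 7e-04 of 10000 shuffles gave a window this full, and no share was computed for other grids. A gained or lost copy is argued against too, as the median log2 fold change of the 28 genes was 0.047 (95% bootstrap interval -0.14 to 0.18). Reads shared with paralogs or pseudogenes stay open, since 7 of the 9 genes were neither ribosomal protein nor predicted genes but shared reads were not measured. A chromosome segment of another strain that differs between these mice could give such neighbours, and stays open too. Genes that stood apart by more than 1 log2 unit in 1 library formed 51 pairs within 5 Mb, against a median of 28 in shuffles, with a share of 0.001, the smallest that 1000 shuffles can give, but without Ctr 1 they formed 16 pairs against 13, with a share of 0.259. Other splits of the libraries, too few for a share under 0.05, gave up to 16 such genes in 1 window against the real 9, and 2 of the 10 splits gave at least 9. That fuller window lay on chromosome 4 from 60 to 65 Mb, around the major urinary protein genes. Windows of 2 Mb held at most 4 low-p genes, windows of 10 Mb 11, and windows shifted by 2.5 Mb 6, on chromosome 17. At an unadjusted p under 0.05 this stretch and a window on chromosome 11 were the fullest, with 12 genes each, and with DESeq2 p-values the stretch was the fullest, with 9 genes. With 1 library left out the stretch itself held 5 to 8 such genes (5 without Ctr 2 or Nbs1-iKO 3), and in 4 of 6 cases a window elsewhere was fuller, with up to 11 genes without Nbs1-iKO 3.

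In Ctr 1, most bile duct epithelium genes stood far above the other libraries, although some, among them Sox9, Slc5a1 and Spp1, did not. Dmbt1, a secreted mucosal glycoprotein gene noticed after the data were seen, stood at 530.6 CPM in Ctr 1 and between 0.34 and 1.28 CPM elsewhere. Muc1 stood at 6.87 against at most 0.58 CPM, and 8 of 12 bile duct markers exceeded the mean of the other libraries by more than 1 log2 unit. A lower share of hepatocytes is argued against, because only 1 of 33 endothelial and macrophage markers did so (exact Fisher test, p = 1.87e-05), although the difference of the medians, 1.92, had a bootstrap interval from -0.14 to 2.56. That Fisher test takes markers of 1 library as independent, so its p does not measure a spread between samples. The bile duct list was taken up because it stood high in Ctr 1, so this p is no independent evidence. Shared, periportal and pericentral hepatocyte genes had median excesses of -0.06, -0.04 and -0.11 in Ctr 1, and its share of counts from Alb, 15.6%, was the highest. A candidate explanation is a piece of gallbladder or large bile duct wall in the sample, since 15 smooth muscle genes had a median excess of 1.69, with Acta2 at 22.4 against at most 6.65 CPM, Myh11 at 22.7 against at most 7.62 CPM and Actg2 at 6.68 against at most 0.45 CPM. The most abundant of the 15, Cald1, did not follow, at 209.6 CPM against 193.3 to 219.1 CPM, and the stellate and fibroblast list, which shares Acta2, had a median excess of 0.07. A change in the bile ducts of this mouse stays open, and no biological explanation was tested because it concerns 1 library.

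In that library the mitosis and G2/M genes had a median excess of 1.44, with 25 of 30 above 1. Erythroid genes had a median excess of 0.96 there, with 4 of 9 above 1. In all, 72 genes stood more than 1 log2 unit above every other library in Ctr 1, against at most 12 in any other library. Ctr 2 stood apart on the low side, with 61 genes more than 1 log2 unit below every other library, against at most 26 in any other, and the neutrophil genes S100a8, S100a9, Mpo and Camp were among the 61. Ren1 and Nlrp12, chosen after their values were seen, lay below the level of 3 counts in Ctr 1, at 0.023 and 0.047 CPM, while the other libraries held 7.50 to 25.8 CPM of Ren1 and 14.2 to 16.7 CPM of Nlrp12.

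Around Nbn on chromosome 4, 6 of 46 tested genes within 5 Mb had an unadjusted p under 0.05, or 13%, against 5.98% elsewhere (exact Fisher test, p = 0.0554). By design the floxed allele is homozygous in Nbs1-iKO and heterozygous in Ctr. Whether the sequence around it also differs between the groups was not tested. Decr1, which encodes an enzyme of fatty acid oxidation and lies next to Nbn, stood at 181 ± 2.1 CPM in Ctr and 154 ± 7.8 CPM in Nbs1-iKO (log2 fold change -0.24), and Gm11844 had -1.78. The other 4 were higher, namely Trp53inp1 (0.49), Dpy19l4 (0.22), Gm11821 (1.03) and Gm11868 (0.45). The rule for named genes had also taken Decr1, from the list of fatty acid oxidation and PPARalpha targets, and Trp53inp1 belongs to the p53 target list. Apart from Decr1 these genes were chosen after their values were seen, and none of the 6 passed the adjusted threshold.

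The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05 for any count. For genes higher in Nbs1-iKO the real count was 0, which all 10 splits reached, and the highest other count in 1 direction was 6. For genes lower the real count was 1, 9 of the 10 splits gave as many in either direction, as the direction of another split is arbitrary, and the highest other was 6. In DESeq2 the real count over both directions was 52, 3 of the 10 splits gave as many, and the highest other was 80. At an unadjusted p under 0.05 the real count was 1038, 3 of the 10 splits gave as many, and the highest other was 1275. For gene lists the real count was 12, 3 of the 10 splits gave as many, and the highest other was 14.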
